A study of Homo sapiens with 6 samples.

How the data were processed

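RNA sequencing of total RNA from cells labelled SW480 gave 6 libraries, 3 untreated controls and 3 treated with TGF-β1 at 10 ng/ml. Each library has its own table of whole-number read counts per gene symbol, which the authors deposited without normalization. Per the submitters' processing notes, the names TopHat2 2.0.11, TopHat and HTSeq and the builds hg19 and GRCh37 belong to this processing, with no role or order stated. The gene annotation, the strand setting and any read filters are not given in the sources used here. Symbols are printed as the deposited count tables give them, and no coordinates are printed because the annotation used here for gene properties is of another build.

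Each table held 56638 gene rows, of which 29131 had a count in at least 1 library. The closing lines of each table are totals of the counter, not genes, and stayed out of library sizes and tests. Reads with no feature made up 5.44% to 5.98% of all lines, ambiguous reads 9.01% to 9.43% and reads aligned to more than 1 place 12.0% to 12.5%, and the lines for unaligned and low-quality reads held 0. Reads that overlap several genes or align to several places are thus missing from the counts, which lowers genes with close copies. Among the 100 most counted symbols 7 are annotated as pseudogenes, and the pseudogene EEF1A1P5, at 3578 CPM in control libraries, stood above its parent gene EEF1A1, at 477 CPM. Total counts per library in genes ran from 13012898 to 16005222.

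Groups and replicate numbers came from the labels. Control and TGFB1 libraries both carry the numbers 1 to 3, and the numbers entered no model unless stated. All pairs of libraries within a group differed by more than sampling noise, with a chi-square of 1.82 to 4.72 per degree of freedom over genes. Separate preparations of the same culture could differ in this way too. Each library was counted as its own replicate, without evidence that it came from a separate culture.

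Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 14897 genes. A gene near the floor in 1 group can pass this filter through the other group alone, which then fixes its direction. Counts were scaled by TMM, with factors of 0.975 to 0.986 in control and 1.015 to 1.024 in TGFB1 libraries, and tested with edgeR's robust quasi-likelihood fit (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The biological coefficient of variation was 0.0470. Adjusted p-values called "edgeR adjusted p" are from this test. CPM values are counts per TMM-scaled library size. Standard errors of log2 fold changes were obtained from the fold change and its F statistic. Where a group had 0 counts, the fold was bounded with 3 counts over the group, and with 1 to 3 counts the ratio was given with an exact 95% interval. Such intervals and floors cover counting error only, since the reads carry no molecular identifiers.

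The 30 gene lists, the rule for named genes, the test and its alternatives were fixed before the data were examined. The rule named 10 fixed genes, the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between groups, up to 4 tested members of each list with the lowest p, and every called member of the acetyltransferase, deacetylase and efflux lists. Some genes under that rule stay in the tests and list counts but are not reported here by name. Genes outside that rule are said to be chosen after their values were seen. Lists were tested with camera (limma) at a preset correlation between genes of 0.01, two-sided, with adjustment over the 30 lists, beside camera with an estimated correlation and fry. Members were also counted with adjusted p over the list alone. A list with few tested members, such as the intestinal, immune and endothelial lists with 2 each, rests on those genes.

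Alternatives were DESeq2, limma-voom, other scalings, other filters on low counts, the replicate number as a block, and leaving out each library in turn. GC and length offsets, a test against a 1.5-fold change and further scalings for the lists were added after the data were seen. GC content and length of the longest GENCODE 29 transcript per symbol, with older symbols matched through RefSeq synonyms, covered 13428 of the 14897 genes (90.1%).

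The tests were tried on simulated counts drawn from the means, library sizes and dispersion of these libraries. For a simulated TGFB1 against control comparison of 14717 genes, 50 genes of at least 1 CPM were changed per fold. Of these, edgeR recovered 60% of genes changed 1.25-fold, 86% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold. It called 0.103% of unchanged genes. In the data 47.3% of genes were called, and the adjustment depends on the share that changes. These rates therefore do not carry over to the data, nor to genes under 1 CPM. Among all 14897 genes, of 29 simulated lists with no change camera called 0. Genes were drawn independently there and only 20 were changed. This cannot show how often camera errs on lists of correlated genes or where many genes change. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.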

Results

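The data were RNA-sequencing counts from cells labelled SW480, a human colorectal adenocarcinoma line, in 2 groups of 3 libraries. The TGFB1 group had received TGF-β1 at 10 ng/ml, and the control group was left untreated. TGF-β1 is a secreted cytokine that signals through the receptor kinases TGFBR1 and TGFBR2 to SMAD transcription factors, and it can drive epithelial cells toward a mesenchymal state. The labels describe repeated treatment and passages 16 to 19 for all libraries, and a total length of exposure is not given in the sources used here. The study's title names histone acetylation, the TGF-β pathway and resistance to chemotherapy, and the gene lists were fixed around these subjects before the data were examined.

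Control libraries 1, 2 and 3 held 13828306, 14803613 and 15298355 counts in genes, and TGFB1 libraries 1, 2 and 3 held 14521761, 16005222 and 13012898. A count of 0 over all 3 control libraries allows a level of up to 0.0698 CPM (read counts of a gene relative to the TMM-scaled library total), and over the 3 TGFB1 libraries up to 0.0677 CPM, counting error only. Log2 CPM values correlated at 0.993 to 0.995 between libraries of a group and at 0.957 to 0.960 between groups, across genes, which are not independent replicates. The first principal component held 81.1% of the variance and separated the groups. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels below are mean CPM ± SD over 3 libraries, and log2 fold changes are TGFB1 minus control ± SE.

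Of 24 tested TGF-β response genes 19 were higher in cells given TGF-β1 than in control cells, 1 was lower and 4 did not pass, with TGFBI, a secreted matrix protein named for its induction by TGF-β, at 677 ± 16.4 CPM against 14.6 ± 2.05. Of 22 listed mesenchymal genes 18 were tested, of which 14 rose and 4 did not pass. CDH2, which encodes N-cadherin, rose from 10.6 ± 0.481 to 74.9 ± 2.43 CPM. Of 10 fibroblast markers 5 had enough counts to be tested, and all 5 rose. Of 16 tested NRF2 targets 15 fell and 1 did not pass, TXNRD1 (thioredoxin reductase) falling from 813 ± 13.4 to 350.2 ± 10.3 CPM, and so did the multidrug efflux pump ABCB1, from 26.2 ± 0.153 to 0.614 ± 0.140 CPM. Of 18 tested histone acetyltransferase genes 11 were lower, by at most 1.58-fold, and 7 did not pass. The calls of all these lists were lost with an estimated correlation between genes (adjusted p = 0.117 for TGF-β response, 0.0577 for mesenchymal genes, 0.344 for fibroblast markers, 0.0577 for NRF2 targets and 0.401 for acetyltransferases).

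Of 14897 genes tested, 7044 (47.3%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3483 higher and 3561 lower with TGF-β1, and 7853 did not pass. The median absolute log2 fold change of the changed genes was 0.45. At least a 2-fold change was seen for 1415 of them, 796 higher and 619 lower, and at least a 4-fold change for 244 higher and 185 lower genes. In 8081 genes (54.2%) the 3 TGFB1 libraries lay entirely above or below the 3 control libraries, where chance gives 10%. When the fold change itself was tested against 1.5-fold, a test chosen after the data were seen, 1646 genes passed.

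**Figure D1:**
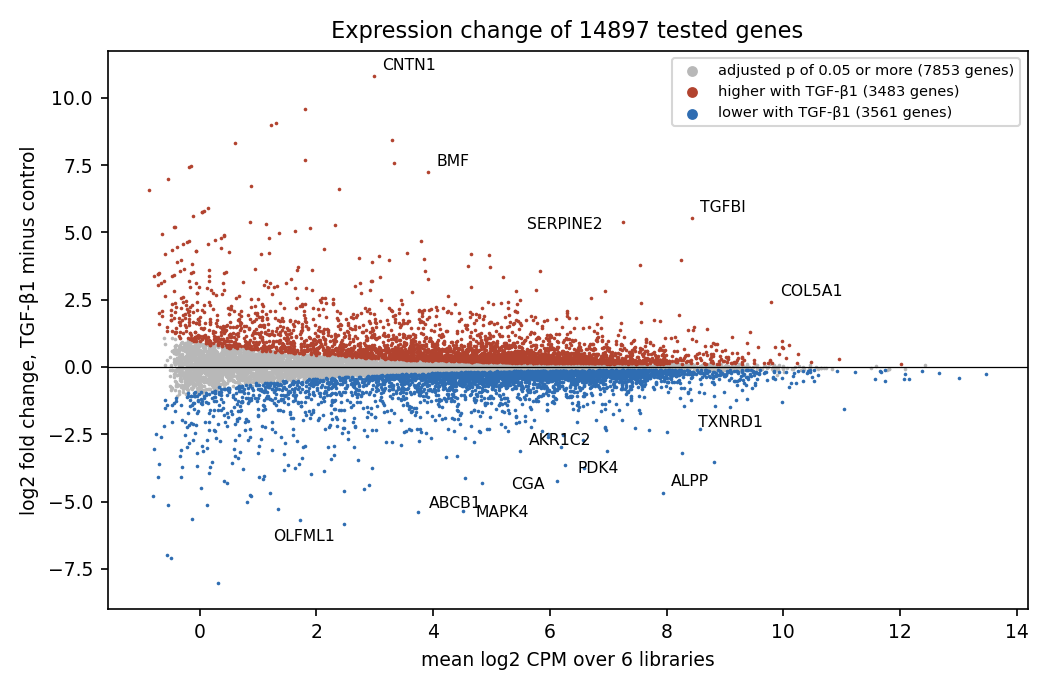
Log2 fold change (TGF-β1 minus control, y axis) against mean log2 CPM over 6 libraries (x axis) for each of 14897 tested genes, 1 point per gene. Red points are the 3483 genes higher with TGF-β1, blue points the 3561 lower and grey points the 7853 with an adjusted p of 0.05 or more; CNTN1 lies at the top and OLFML1 and ABCB1 in the lower left.

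The very largest rises among well-counted genes were in genes nearly silent in control cells. TGFBI and SERPINE2, also among the 10 largest, were not, at 14.6 and 7.20 CPM there. CNTN1, which encodes the neural adhesion protein contactin 1, had 0 counts in the control libraries and 15.4 ± 0.425 CPM with TGF-β1, at least 220.5-fold higher against the floor of 3 counts over the group (edgeR adjusted p = 2.83e-18). MARCH4, a membrane-bound ubiquitin ligase, had 2 control counts and 842 TGFB1 counts, a ratio of 408 after scaling with a 95% counting interval of 113 to 3378. MYOM3 (myomesin 3), BMF (a BH3-only cell death protein) and INPP4B (a phosphoinositide phosphatase) rose to 19.4 ± 1.44, 29.3 ± 2.04 and 10.0 ± 0.175 CPM from control levels of 0.188 CPM or less. The sizes of these folds are uncertain, since they rest on few control counts, 4 for MYOM3 and 8 for BMF, and leaving out control 3 moved the log2 fold change of BMF from 7.24 to 6.63. SERPINE2 (protease nexin 1), RAB3B (a vesicle GTPase) and ACTC1 (cardiac α-actin) rose 41.4-fold, 38.8-fold and 25.9-fold. RP1-74M1.3, known only by a clone name, rose 20.9-fold. Whether the counter used strand is not given in the sources used here, so its reads cannot be separated from those of any overlapping gene.

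The largest falls were in OLFML1, an olfactomedin-like secreted protein, from 10.8 ± 1.03 to 0.182 ± 0.0453 CPM (57.0-fold lower, edgeR adjusted p = 6.17e-17), and in ABCB1 (42.4-fold lower, edgeR adjusted p = 4.38e-21). MAPK4, an atypical MAP kinase, was 40.9-fold lower, and VTN (vitronectin) and KCND3 (a potassium channel) were 24.2-fold and 23.3-fold lower. ALPP, placental alkaline phosphatase, fell from 473 ± 17.2 to 18.6 ± 1.05 CPM, and CGA, the α subunit shared by the pituitary and placental glycoprotein hormones, from 133 ± 1.98 to 7.0 ± 0.565 CPM. ALPP has near-identical relatives, so its level is uncertain where the counting could split reads among them. ALDH3A1, an aldehyde dehydrogenase, was 20.7-fold lower, and the chemokine CXCL16 17.4-fold lower. PAPPA2, a protease of insulin-like growth factor binding proteins, fell from 54.3 ± 4.52 to 2.69 ± 0.431 CPM.

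Of 24 tested members of the TGF-β response list, 19 rose, 1 fell and 4 did not pass, with the same 19 and 1 when adjusted over the list alone and a median log2 fold change of 1.38. Besides TGFBI (5.53 ± 0.070, edgeR adjusted p = 1.40e-29), PMEPA1, a brake on the pathway, rose from 25.1 ± 2.32 to 349 ± 8.13 CPM and the cytokine IL11 from 6.54 ± 1.08 to 66.2 ± 2.11 CPM. SMAD7, the inhibitory SMAD, rose 2.39-fold, from 18.2 ± 1.70 to 43.5 ± 4.19 CPM (edgeR adjusted p = 3.96e-13). The list as a whole ranked above other genes (camera adjusted p = 1.63e-09), and this call was lost with the correlation between its genes estimated from the data (adjusted p = 0.117 with an estimated correlation).

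Components of the pathway moved in both directions. Among 18 tested ligands, receptors and SMADs, 9 rose, 4 fell and 5 did not pass, the same 9 and 4 when adjusted over the list alone, and the list was not called (median 0.21, camera adjusted p = 0.253). TGFBR1 rose from 101 ± 7.45 to 340.0 ± 3.78 CPM (edgeR adjusted p = 4.20e-21) and the TGFB1 gene from 71.5 ± 0.559 to 155 ± 3.62 CPM (edgeR adjusted p = 8.77e-17). TGFBR3, the co-receptor betaglycan, fell 2.58-fold, and the receptor-activated SMAD2 and SMAD3 fell by 0.72 and 0.58 on the log2 scale. SMAD4, the shared partner of these SMADs, stood at 32.9 ± 2.10 and 35.7 ± 0.592 CPM and did not pass (edgeR adjusted p = 0.172), but it passed with scaling by library size alone (edgeR adjusted p = 0.0432) and with GC and length offsets (edgeR adjusted p = 0.00859). TGFBR2 rose only 1.14-fold (edgeR adjusted p = 0.0128), a call that ended without control 2, control 3 or TGFB1 2 (edgeR adjusted p = 0.0584, 0.0606 and 0.162). Of 9 tested BMP and ID targets 5 rose, 1 fell and 3 did not pass (5 and 2 adjusted over the list alone, median 0.18, camera adjusted p = 0.297). ID1 and ID3, inhibitors of basic helix-loop-helix factors, rose 1.68-fold and 1.94-fold, and HEY1 and SMAD6 rose 2.48-fold and 1.56-fold.

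**Figure D2:**
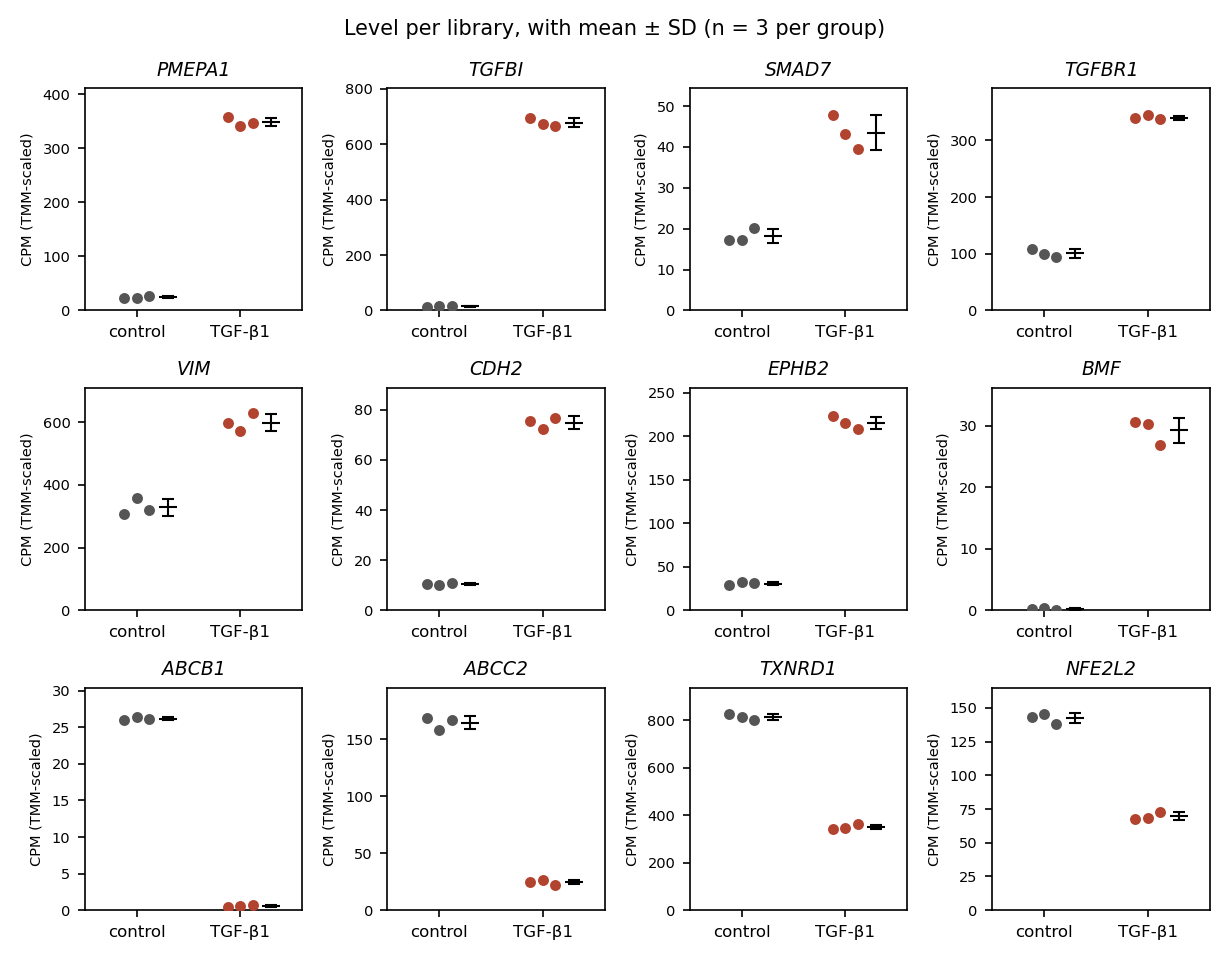
CPM (y axis, TMM-scaled, from 0) of 12 genes in each of 3 control libraries (grey points) and 3 TGF-β1 libraries (red points), with the mean ± SD of each group as a black bar. The points of the groups do not overlap in any of the 12 panels, with TGFBI at 677 CPM against 14.6 and ABCB1 at 0.614 CPM against 26.2.

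Most tested mesenchymal genes rose and most tested epithelial genes fell. Of 22 listed mesenchymal genes 18 were tested. The others, ACTA2, SPARC, PRRX1 and CDH11, stood at 0.566 CPM or less in both groups. Of the 18 tested 14 rose, 0 fell and 4 did not pass (15 and 0 adjusted over the list alone), with a median log2 fold change of 1.08 (camera adjusted p = 2.72e-07, adjusted p = 0.0577 with an estimated correlation). MMP2, chosen after its values were seen, rose from 0.0721 to 1.84 CPM. It passed the count filter only through the TGFB1 libraries, which fixed its place among the rises. COL5A1, a fibrillar collagen chain, rose from 282 ± 16.3 to 1496 ± 60.5 CPM, and LOX, which crosslinks collagen, from 13.2 ± 1.33 to 95.1 ± 3.15 CPM. CDH2 rose 7.07-fold, the fibronectin receptor subunit ITGA5 3.29-fold and the intermediate filament gene VIM 1.82-fold, from 329 ± 26.9 to 599 ± 28.4 CPM (edgeR adjusted p = 9.72e-14). Of 22 listed epithelial genes 15 reached 1 CPM in control cells, and only these were tested. The others were thus low or absent already in untreated cells. Of the 15 tested epithelial genes 3 rose, 10 fell and 2 did not pass, the same 3 and 10 adjusted over the list alone (median −0.64, camera adjusted p = 0.0188, adjusted p = 0.193 with an estimated correlation). JUP (plakoglobin) fell from 613 ± 19.5 to 289 ± 20.3 CPM, ST14 (matriptase) 2.77-fold and KRT18 1.47-fold, while DSP (desmoplakin), a desmosome protein as JUP is, rose 1.80-fold. CDH1, which encodes E-cadherin, was already low in control cells, at 1.09 ± 0.0707 CPM (47 counts over 3 libraries), and fell to 0.271 ± 0.176 CPM (12 counts, edgeR adjusted p = 0.000610).

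Matrix remodelling and integrin genes rose in 13 of 20 tested, fell in 3 and did not pass in 4, with the same 13 and 3 adjusted over the list alone (median 0.69, camera adjusted p = 0.00259, adjusted p = 0.193 with an estimated correlation). The basement membrane collagens COL4A1 and COL4A2 rose 2.45-fold and 1.98-fold, to 974 ± 22.6 and 1333 ± 39.0 CPM. PLAUR, the urokinase receptor, rose 2.30-fold and the collagen receptor subunit ITGA2 3.61-fold. Markers of fibroblasts moved with these groups: of 10 such genes, 3 reached 1 CPM in control cells, 5 were tested and all 5 of these rose, 5 and 0 adjusted over the list alone (median 1.12, camera adjusted p = 0.00457, adjusted p = 0.344 with an estimated correlation). COL1A1 rose from 81.3 ± 2.64 to 105 ± 5.40 CPM, DCN (decorin) from 3.37 ± 0.0921 to 7.54 ± 0.920 CPM and PDGFRB from 7.99 ± 0.373 to 14.8 ± 2.01 CPM. FAP had 1 control count and 51 TGFB1 counts, a ratio of 49.5 with a 95% counting interval of 8.49 to 1992. It passed the count filter only through the TGFB1 libraries, so its place among the tested markers that rose was fixed by the filter.

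Genes of histone acetyltransferases, the enzymes that add acetyl groups to histones, were lower in 11 of 18 tested, higher in 0 and did not pass in 7 (1 higher and 11 lower adjusted over the list alone, 2 higher and 9 lower with scaling by library size alone). The median log2 fold change was −0.25 (camera adjusted p = 0.0188), a call lost with an estimated correlation (adjusted p = 0.401 with an estimated correlation). KAT2B (PCAF) fell from 15.5 ± 1.09 to 9.80 ± 0.364 CPM (edgeR adjusted p = 6.30e-06). The paralogous coactivators EP300 and CREBBP fell by 0.29 and 0.26 on the log2 scale (edgeR adjusted p = 0.00134 and 0.00197). TAF1, KAT6A, KAT7, NCOA2, ELP3 and NAA60 fell by 0.25 to 0.35. NCOA1 and CLOCK fell by 0.24 and 0.25, and their calls ended without control 1 (edgeR adjusted p = 0.228 and 0.0515), without TGFB1 3 (0.0638 and 0.0895), in DESeq2 (DESeq2 adjusted p = 0.139 and 0.0712) and with scaling by library size alone (edgeR adjusted p = 0.114 and 0.0610). NCOA1 also lost its call without TGFB1 1 (edgeR adjusted p = 0.137).

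Genes of the opposing enzymes, histone deacetylases and sirtuins, rose in 6 of 17 tested, fell in 4 and did not pass in 7, the same 6 and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.575, median 0.05, mean −0.0086). HDAC5 rose 1.48-fold, from 63.2 ± 0.857 to 93.3 ± 7.83 CPM (edgeR adjusted p = 1.12e-08), SIRT6 1.34-fold, HDAC7 1.20-fold, HDAC3 1.15-fold and HDAC2 1.14-fold. HDAC9 fell from 7.06 ± 0.275 to 3.67 ± 0.637 CPM, HDAC4 1.31-fold and SIRT7 1.30-fold. SIRT1 and SIRT2 lay at the threshold (edgeR adjusted p = 0.0488 and 0.0473). SIRT1 lost its call without any library other than control 1 (edgeR adjusted p = 0.0583 to 0.245), SIRT2 without control 2, control 3, TGFB1 2 or TGFB1 3 (0.0940 to 0.139), and HDAC3 without control 1 (0.0739). SIRT1 and SIRT2 did not pass in DESeq2 (DESeq2 adjusted p = 0.159 and 0.176) or with the replicate number as a block (edgeR adjusted p = 0.0882 and 0.0749). Bromodomain proteins, which bind acetylated lysines, rose in 2 of 23 tested, fell in 9 and did not pass in 12, the same 2 and 9 adjusted over the list alone (median −0.09, camera adjusted p = 0.395). This lean depends on the scaling, as 6 rose and 5 fell with scaling by library size alone. BAZ1A rose 1.42-fold, PHIP fell 1.52-fold, ATAD2B 1.39-fold and TRIM24 1.17-fold.

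Drug efflux transporters fell in 7 of 13 tested, rose in 2 and did not pass in 4, the same 2 and 7 adjusted over the list alone. The median log2 fold change was −0.24 and the mean −0.90 (camera adjusted p = 0.0223, adjusted p = 0.470 with an estimated correlation). After ABCB1, the pump also known as P-glycoprotein, the largest falls were in ABCC2, an exporter of conjugated drugs, from 164 ± 5.74 to 24.7 ± 2.09 CPM (edgeR adjusted p = 1.85e-23), and in ABCG2, the breast cancer resistance protein, from 9.61 ± 0.748 to 1.78 ± 0.507 CPM (edgeR adjusted p = 4.22e-12). ABCA2 fell 1.68-fold, ABCC5 1.41-fold and ABCC4 1.18-fold. ABCC3 rose 1.33-fold, from 27.3 ± 1.01 to 36.2 ± 2.51 CPM, and ABCC10 1.17-fold (edgeR adjusted p = 0.0298). The ABCC10 call ended without control 1, control 2, TGFB1 2 or TGFB1 3 (edgeR adjusted p = 0.160, 0.0589, 0.0634 and 0.0672) and in DESeq2 (DESeq2 adjusted p = 0.133).

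Genes of chemotherapy drug targets and metabolism went both ways, with 4 of 24 tested higher, 8 lower and 12 not past the test (5 and 9 adjusted over the list alone, and 7 and 6 with scaling by library size alone). The median log2 fold change was −0.07 and the mean 0.08, and the list was not called (camera adjusted p = 0.840). SLC29A1, a nucleoside transporter that takes up nucleoside drugs, rose from 62.7 ± 2.42 to 171 ± 5.90 CPM. DPYD, which degrades fluorouracil, rose 3.28-fold and TYMP (thymidine phosphorylase) 1.88-fold, while GSTP1, a glutathione transferase, fell 1.59-fold.

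Cell death genes were likewise mixed. Of 9 tested anti-apoptotic genes 2 rose, 4 fell and 3 did not pass (median 0.06, mean −0.19, camera adjusted p = 0.723), and of 19 tested pro-apoptotic genes 5 rose, 5 fell and 9 did not pass (median −0.01, mean 0.30, camera adjusted p = 0.991), both with the same counts adjusted over the list alone. BCL2 fell 3.13-fold and BIRC3 1.64-fold, while MCL1 and XIAP rose 1.33-fold and 1.44-fold. Of the pro-apoptotic genes with the lowest p, BMF rose as given above, BCL2L11 (BIM) 1.76-fold and BID 1.45-fold, while the initiator caspase gene CASP9 fell from 69.2 ± 4.43 to 16.2 ± 0.817 CPM (edgeR adjusted p = 2.18e-19).

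Of 15 tested WNT/β-catenin targets 8 rose, 6 fell and 1 did not pass, and the list was not called (median 0.50, camera adjusted p = 0.219). The receptor kinase gene EPHB2 rose from 30.7 ± 1.59 to 215 ± 7.09 CPM (edgeR adjusted p = 1.11e-24), MYC 2.14-fold, TCF7 2.60-fold and CCND1 1.52-fold. Of 17 listed genes associated with stem cells 8 reached 1 CPM in control cells and 9 were tested. These rose in 7 of 9, fell in 0 and did not pass in 2 (median 0.62, camera adjusted p = 0.00259, adjusted p = 0.162 with an estimated correlation). CD44, the hyaluronan receptor, rose from 197 ± 1.61 to 505 ± 18.4 CPM, LRIG1 3.01-fold, SOX9 4.42-fold and KLF4 1.52-fold. MAPK feedback genes rose in 12 of 15 tested, fell in 2 and did not pass in 1 (median 0.80, camera adjusted p = 0.00271, adjusted p = 0.193 with an estimated correlation), with IER3 5.12-fold, ETV5 2.54-fold, ETV4 1.88-fold and SPRED2 1.74-fold higher. YAP and SRF targets split into 7 higher, 5 lower and 1 not past the test among 13 tested (median 0.22, camera adjusted p = 0.395). F3 (tissue factor), AXL and CYR61 rose 4.62-fold, 2.11-fold and 1.93-fold, and TEAD1, a partner of YAP, fell 1.49-fold. These 4 lists gave the same counts adjusted over the list alone.

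NRF2 targets, which encode antioxidant and NADPH-producing enzymes, gave the lowest camera p of the 30 lists. Of 16 tested 15 fell, 0 rose and 1 did not pass, the same adjusted over the list alone, with a median log2 fold change of −1.25 (camera adjusted p = 1.94e-10, adjusted p = 0.0577 with an estimated correlation). TXNRD1 fell 2.32-fold (edgeR adjusted p = 7.32e-19) and GSR (glutathione reductase) from 230.1 ± 0.501 to 89.1 ± 3.48 CPM (edgeR adjusted p = 3.26e-19). The aldo-keto reductase genes AKR1C2 and AKR1C3 fell 8.80-fold and 3.88-fold, and since these are near-identical copies their separate levels are uncertain.

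Other metabolic lists moved less. Cholesterol synthesis genes fell in 13 of 18 tested, rose in 1 and did not pass in 4, the same 1 and 13 adjusted over the list alone (median −0.19, camera adjusted p = 0.0109, adjusted p = 0.538 with an estimated correlation). With scaling by library size alone only 7 fell and 1 rose. SREBF2, the transcription factor that governs the pathway, fell 1.46-fold, MVD 1.41-fold and LSS 1.23-fold. Hypoxia and glycolysis genes were higher in 2, lower in 6 and not past the test in 10 of 18 tested (median −0.13, camera adjusted p = 0.106). PFKFB4 rose 2.27-fold, and BNIP3, GAPDH and ALDOA fell 1.80-fold, 1.35-fold and 1.30-fold. Of 16 tested genes of the unfolded protein and integrated stress responses 2 rose, 8 fell and 6 did not pass (median −0.19, camera adjusted p = 0.106), with the splicing-activated factor XBP1 1.32-fold, the chaperone HSPA5 1.22-fold and TRIB3 1.24-fold lower. SDF2L1, an endoplasmic reticulum protein, fell by 0.33 on the log2 scale. The latter pair of lists gave the same counts adjusted over the list alone.

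Proliferation genes rose in 4, fell in 10 and did not pass in 8 of 22 tested (median −0.05, camera adjusted p = 0.332). The mitotic kinase gene AURKA fell 1.46-fold, TOP2A 1.26-fold and BUB1 1.21-fold, while CCNE1 (cyclin E1) rose 1.61-fold. Of 16 tested p53 targets 4 rose, 8 fell and 4 did not pass (median −0.22, camera adjusted p = 0.219), with MDM2, CCNG1 and GDF15 lower by 1.64-fold, 1.70-fold and 2.49-fold and TP53I3 higher by 1.71-fold. Interferon response genes were higher in 3, lower in 6 and not past the test in 9 of 18 tested (3 and 8 adjusted over the list alone, median −0.0085, mean −0.22, camera adjusted p = 0.261). OAS3, OAS1, IFI6 and BST2 fell 2.13-fold, 2.75-fold, 3.06-fold and 1.46-fold. Of 9 tested NF-κB and cytokine targets 2 rose, 3 fell and 4 did not pass (median −0.02, mean 0.22, camera adjusted p = 0.528). The feedback inhibitors TNFAIP3 and NFKBIA fell 1.59-fold and 1.57-fold, NFKB2 fell 1.38-fold, and IL8 rose from 0.182 ± 0.157 to 1.13 ± 0.168 CPM. Apart from the interferon list, these lists gave the same counts adjusted over the list alone.

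Of 19 intestinal differentiation genes 2 reached 1 CPM in control cells, and both were tested and fell, also when adjusted over the list alone (median −2.99, camera adjusted p = 0.0108, adjusted p = 0.193 with an estimated correlation). HNF4A, a transcription factor of liver and gut, fell from 10.3 ± 1.56 to 2.20 ± 0.158 CPM. ALPI, intestinal alkaline phosphatase, fell from 179 ± 12.3 to 13.1 ± 2.00 CPM, but it is a near-identical relative of ALPP and its counts are uncertain. Of 10 immune markers 2 were tested, with 1 higher, 0 lower and 1 not past the test (median 1.29, camera adjusted p = 0.261). CSF1R rose from 0.669 ± 0.204 to 3.27 ± 0.487 CPM. Of 7 endothelial markers 2 were tested, with 0 higher, 1 lower and 1 not past the test (median −1.32, camera adjusted p = 0.253). VWF fell from 2.66 ± 0.419 to 0.510 ± 0.192 CPM, and ERG stood at 2.46 ± 0.547 and 2.04 ± 0.752 CPM. Both lists kept these counts when adjusted over the list alone.

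Transcripts of the mitochondrial genome, measured as a sign of RNA quality, took 5.72% ± 0.199 of the counts in control libraries and 4.87% ± 0.0588 in TGFB1 libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Of 13 such genes 10 fell, 0 rose and 3 did not pass, the same adjusted over the list alone (median −0.22, camera adjusted p = 0.00267, adjusted p = 0.426 with an estimated correlation). MT-ND1 fell by 0.51, MT-ND5 by 0.44 and MT-ND4 and MT-ND6 by 0.41 on the log2 scale.

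**Figure D3:**
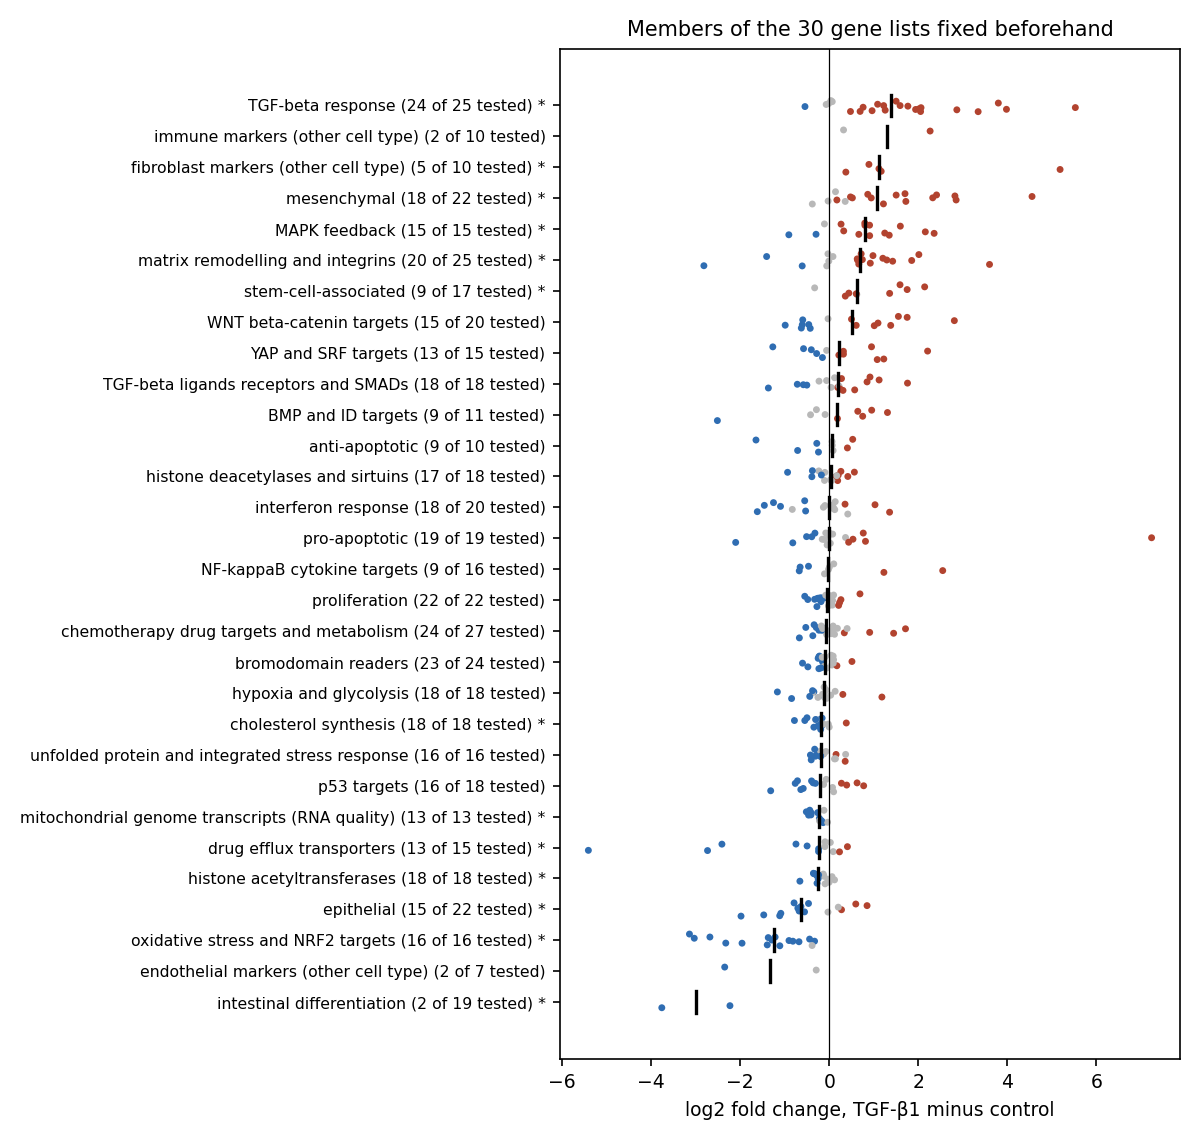
Log2 fold changes (TGF-β1 minus control, x axis) of the tested members of the 30 gene lists fixed before the data were examined, 1 row per list, 1 point per gene and a black bar at each list's median. Red and blue points passed the test as higher or lower and grey points did not, and an asterisk marks the 13 lists called by camera with a preset correlation, from the TGF-β response list (median 1.38) to the intestinal list (median −2.99); 0 lists were called with an estimated correlation.

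With the preset correlation 13 of the 30 lists were called, 6 higher and 7 lower. With a correlation estimated from the data 0 were called, 6 had an unadjusted p under 0.05, and the lowest adjusted p was 0.0577, while the rotation test fry, which asks only whether a list's genes move on balance in either direction, called 28. Among the 13 lists the estimate ran from −0.050 (epithelial) to 0.638 (cholesterol synthesis), against the preset 0.01. In simulated counts with genes drawn independently, estimating it raised the camera adjusted p of a moved list from 1.22e-36 to 0.0104. The estimate thus raised p without correlated genes, but the simulated list kept its call. The simulation therefore cannot tell which of the 13 lost calls reflect correlated genes.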

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

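GC and length offsets, the 1.5-fold test and the library-size and upper-quartile scalings of the lists were chosen after the data were seen, and the other alternatives before. Against 7044 changed genes, DESeq2 called 5748 (5575 of them shared), limma-voom 6978 (6927 shared), edgeR with median-of-ratios factors 7024, with upper-quartile factors 7018 and with GC and length offsets 7078. Without a filter 7111 genes were called, and with at least 1 CPM in 3 libraries 6895. Scaling by library size alone called 7095, 4216 higher and 2879 lower, so that 59.4% of changed genes were higher against 49.4% with TMM, and the median log2 fold change of all genes was 0.06. Leaving out each library in turn gave 6115 to 6816. Tested against a 1.5-fold change 1646 genes passed, 909 higher and 737 lower, 1266 of them changed at least 2-fold, because the test asks for more than any change.

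The expression values gave no sign that the replicate numbers pair the libraries, though a weak shared effect is not excluded. Deviations from the group means correlated at 0.03, −0.11 and −0.05 between libraries of the same number, across genes, and not every library correlated best with its own number. With the replicate number as a block 6775 genes were called, 3355 higher and 3420 lower, and 6692 were shared.

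All 168 named genes were tested in each setting, except with the stricter filter (165) and with GC and length offsets (167). No gene called in the main test or in a setting changed direction in that setting. Changes of sign in genes called in neither were not counted. Of these genes, those chosen after their values were seen included, 5 lost their call in DESeq2, 0 in limma-voom, 3 with scaling by library size, 2 with upper-quartile factors (NCOA1 and SIRT2), 1 with median-of-ratios factors (SIRT2), 3 with no filter (SIRT1, SIRT2 and ABCC10), 2 with the block (SIRT1 and SIRT2), 2 with GC and length offsets (NCOA1 and CLOCK), 2 to 5 on leaving out a library and 66 against a 1.5-fold change, where the other genes tested kept theirs or stayed uncalled. With GC and length offsets FOLR1 and SMAD4 gained a call (edgeR adjusted p = 0.00431 and 0.00859), and SMAD4 did so with scaling by library size (0.0432). All 13 list calls held with the stricter filter, the block and each left-out library. They also held with each scaling, but camera sets a list against the other genes and a scaling shifts all genes nearly alike. A change of scaling could therefore hardly move these calls, although it did move counts of called members. With an estimated correlation 0 lists were called by camera, and fry called 28. Fry put the chemotherapy list on the higher side (fry adjusted p = 0.0362), where camera put it on the lower, and the cause was not tested. Depth limits the low genes: CDH1, FAP, MARCH4, MYOM3 and BMF rest on 1 to 47 counts over the control libraries.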

Other observations

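The gene families and the aryl hydrocarbon receptor, urea cycle and HeLa lists in this part, the single genes named with them, and the tests made in this part were chosen only after the results were seen, except the count over splits of the libraries. The NRF2 and intestinal lists and their tests by edgeR were fixed before. Collagen genes rose in 17 of 25 tested and fell in 3 (camera adjusted p = 0.000892 over 12 families and lists, adjusted p = 0.377 with an estimated correlation). Of those that rose, COL17A1 and COL20A1 stood at 0.140 and 0.0952 CPM in control libraries. They passed the count filter only through the TGFB1 libraries, which fixed their place among the rises. COL7A1, the collagen of anchoring fibrils, rose from 755 ± 23.2 to 1262 ± 41.0 CPM and COL4A3 from 4.19 ± 1.07 to 16.6 ± 1.65 CPM, while COL9A3, a cartilage collagen, fell from 26.2 ± 1.43 to 11.7 ± 2.23 CPM. Integrin subunit genes rose in 12 of 18 tested and fell in 2 (camera adjusted p = 0.000255, adjusted p = 0.137 with an estimated correlation). ITGA11, a collagen receptor subunit, rose from 0.0943 ± 0.0455 to 3.98 ± 0.212 CPM and ITGB3 from 0.763 ± 0.153 to 5.94 ± 0.878 CPM, while ITGB8, which takes part in activating latent TGF-β, fell from 2.87 ± 0.570 to 0.432 ± 0.0943 CPM. ITGA11 passed the count filter only through the TGFB1 libraries and ITGB8 only through the control libraries, which fixed their directions. Genes of the ABC transporter family, which includes pumps not on the efflux list, fell in 15 of 30 tested and rose in 4 (camera adjusted p = 0.0154, adjusted p = 0.377 with an estimated correlation). Aldo-keto reductase genes, some of them also on the NRF2 list, fell in 7 of 9 tested and rose in 0 (camera adjusted p = 0.000255, adjusted p = 0.204 with an estimated correlation). Nuclear-encoded complex I subunits fell in 12 of 37 tested and rose in 1 (camera adjusted p = 0.0439, adjusted p = 0.674 with an estimated correlation). Laminins, mitochondrial and cytosolic ribosomal proteins, proteasome subunits and myosin and tropomyosin genes were not called (camera adjusted p = 0.187 to 0.799).

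Genes of the aryl hydrocarbon receptor, a ligand-activated transcription factor that senses xenobiotics, fell in 4 of 5 tested and rose in 1 (camera adjusted p = 0.00495, adjusted p = 0.196 with an estimated correlation). Its repressor gene AHRR fell from 553 ± 10.6 to 60.1 ± 4.40 CPM and the cytochrome P450 gene CYP1B1 from 34.1 ± 2.35 to 3.34 ± 0.256 CPM, TIPARP rose 1.29-fold, and the receptor gene AHR itself fell from 43.0 ± 5.77 to 20.5 ± 2.47 CPM. The list was chosen with values already seen. It holds ALDH3A1, already among the 10 largest falls, and NQO1 from the NRF2 list, so its p-value cannot decide whether the receptor's targets fell. The urea cycle and arginine genes were not called as a list (1 higher and 3 lower of 7 tested, camera adjusted p = 0.187), yet they hold abundant transcripts that fell: ASS1, which makes argininosuccinate, from 3129 ± 58.4 to 1064 ± 27.6 CPM, and CPS1, the entry enzyme of the cycle, from 1446 ± 81.3 to 579 ± 19.9 CPM (edgeR adjusted p = 2.34e-21 and 5.79e-19). ASL, the enzyme after ASS1, rose 1.69-fold.

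Genes of intestinal identity were near the counting floor in the control libraries: CDX2, the intestinal homeobox factor, had 0 counts, VIL1 (villin) 3 and KRT20 4 over 3 libraries, and KRT19 had 1, beside 1711 ± 1.33 CPM of KRT8. Too little depth is argued against, since 0 counts over 3 control libraries allow at most 0.0698 CPM. Another cell line than the label gives is a candidate explanation, but the 2 of 19 intestinal genes that reached 1 CPM only restate what it would explain, so it stays open. A loss of intestinal identity within SW480 cells cannot be told apart from it by expression, with 17 of 41 intestinal and epithelial genes at 1 CPM, and sequence variants would be needed. HeLa cells, which are known for CDKN2A, placental alkaline phosphatase, glycoprotein hormone α subunit and folate receptor expression, might be such a line: CDKN2A, CGA, ALPP and FOLR1 stood at 119, 133, 473 and 1594 CPM, but the 4 genes were picked from these libraries, so their levels cannot decide it.

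The fall of 15 of 16 tested NRF2 targets was weighed against technical causes and against lower aryl hydrocarbon receptor activity. The choice among 4 library scalings shifted genes too little to account for the fall. The median log2 fold change of all genes lay between 0.0003 and 0.057 under them, and that of the list between −1.25 and −1.19. With shifts so small the result was fixed beforehand, so it tests no other fault of scaling. Reads shared among the near-identical aldo-keto reductase genes are argued against as the whole cause, because 11 of the 12 other members fell. Lower aryl hydrocarbon receptor activity stays open: besides NQO1, which is on both lists, 3 of its targets fell and 1, TIPARP, rose. That list was chosen after its values were seen, and its targets other than NQO1 are not on the NRF2 list, so they cannot decide it. NFE2L2, which encodes NRF2, fell from 142 ± 3.72 to 69.6 ± 2.99 CPM and its inhibitor gene KEAP1 from 49.2 ± 4.83 to 42.0 ± 0.520 CPM, and levels of the proteins were not measured here.

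The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 7044 changed genes, as many as in 1 of the 10. The highest of the others gave 0 by edgeR and 0 by DESeq2, with at most 314 genes at an unadjusted edgeR p under 0.05. Every other split mixes control and TGFB1 libraries in both arms, so the difference between the groups counts there as spread within arms. Few or no calls were thus fixed beforehand, and the splits cannot decide whether chance made the 7044.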
